A study of Homo sapiens with 8 samples.

How the data were processed

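The series holds strand-specific RNA-seq of H1 cells at 4 stages of directed differentiation, 2 libraries per stage. Per the labels' protocols, total RNA was depleted of ribosomal RNA, libraries were made with dUTP marking so that strand was kept, and sequencing was paired-end on a HiSeq instrument. The hESC and hDE libraries are marked as re-analysed in the labels' titles. The deposited tables are gene-level RSEM output, per the file headers and the submitters' processing notes, which also name DESeq2 and the build hg38 without versions. The aligner is not given in the sources used here. The deposited expected counts are estimated counts in which reads that fit several genes are split between them. The deposited TPM values are transcript shares that allow for effective length, per the file headers. The deposited effective lengths and the deposited posterior standard deviations of the counts were read as other columns; the first served in an alternative and the second as a value per gene beside the named genes.

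Each table had 59526 rows. Of these 58780 carried gene identifiers that all matched GENCODE 29, from which symbols and hg38 positions were taken, and 97 spike-in and 649 tRNA rows held 0 counts in every library. Mitochondrial ribosomal RNA took 10.6% to 18.4% of the counts and 7SL RNA 3.78% to 18.2%. The second hPFE library held both the highest mitochondrial share and the lowest 7SL share. The hDE libraries held the highest 7SL shares. A total of 0 allows up to 3 counts over the 2 libraries of a stage, or 0.0874 CPM in hESC, 0.12 in hDE, 0.104 in hAFE and 0.0989 in hPFE. Folds against a stage at 0 are bounds against that floor, and folds against 1 to 3 counts carry an exact 95% binomial interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Genes with close copies, such as POU5F1, NANOG, PRSS2, LEFTY1 with LEFTY2, the histone and mitochondrial genes, and the 7SL genes, could have reads split between copies. The deposited posterior standard deviation was 0.627 of the count for AL356488.2, 0.257 for LINC00261 and 0.051 for RN7SL1, which are uncertain, and lower for every other named gene.

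Expected counts were rounded to whole numbers and filtered with filterByExpr, which left 17446 genes. One model over all 8 libraries with 4 stage terms and 4 residual degrees of freedom was fitted with edgeR 4.0.16 (TMM scaling, quasi-likelihood test, Benjamini-Hochberg adjustment over all genes, threshold 0.05) in R 4.3.3. Sharing the spread across stages assumes that they vary alike. Levels are CPM after TMM scaling. The SE beside a log2 fold change is its absolute value divided by the square root of the test's F statistic. It is not a separately fitted standard error. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01; 39 lists were fixed, 37 had at least 4 measured members, and the 148 list tests over 4 comparisons were adjusted together. Of these, 65 were called, and none held with a correlation estimated from the data, for which the lowest adjusted p was 0.132. The estimated form refers to 4 residual degrees of freedom. A call lost in that form therefore need not reflect correlated genes.

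Groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Which of the lists to describe in each comparison was chosen after their tests were seen, so the members named from them follow from that choice. The rule took 8 landmarks in every comparison, the 4 largest rises and 4 largest falls among called genes at 10 CPM or more in the higher stage with non-overlapping libraries, and from each described list up to 4 called members, 2 called the other way and 2 of the best expressed that did not pass. For 2 libraries against 2, chance gives non-overlapping libraries in 33.3% of genes. The stage-high genes passed against each of the other stages.

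Alternatives were RLE scaling, DESeq2 1.42.0, no count filter, a filter of 1 CPM in 2 libraries, only the 4 libraries compared, a replicate block, effective length offsets, limma on log2(TPM + 1), a minimum of 2 fold, leaving out small structural, mitochondrial and histone genes, and leaving out each library. The TPM values were used as deposited, without TMM scaling, in the gene and the list tests. A limma voom fit with a weight per stage was added after seeing the data. When a library is left out its stage has 1 library, which is then assumed to vary like the others. The edgeR step was tested on simulated data. For simulated hDE vs hESC with 15903 genes and 200 changed, 35% of 2-fold and 84% of 4-fold changes were recovered. There 9 calls (7.03% of calls) were false, while simulated hPFE vs hAFE with no changed gene gave 0 calls. All simulated libraries were drawn from hESC means, with the spread of each gene shared by all stages. The 0 calls therefore do not test the case of stages that vary unequally. The changed genes were drawn only from genes above a minimum expected count. The recovery rates therefore do not cover genes with low counts. Genes of the sex chromosomes used to tell sex apart, and some other genes that the rule took, are not reported here.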

Results

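RNA was profiled at 4 stages of a stepwise culture that takes H1 cells, an established human embryonic stem cell line, towards the endoderm that lines the embryonic pharynx. The cells were sampled undifferentiated (hESC), as definitive endoderm (hDE), then as endoderm of the anterior foregut (hAFE) and lastly of the pharyngeal foregut (hPFE), with 2 libraries per stage and 8 in all. The hESC and hDE libraries were re-analysed from earlier deposits and the hAFE and hPFE libraries were new. The labels do not say whether the 2 libraries of a stage came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Levels are CPM, counts scaled to library size with TMM factors, given as mean ± SD with n = 2, and the adjusted p of a gene comes from edgeR's quasi-likelihood test over 17446 genes, that of a gene list from camera over 148 list tests. Positions are on hg38.

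Libraries grouped by stage. The first principal component of log2 CPM held 41.5% of the variance and separated hESC and hDE from hAFE and hPFE. That split is also the split between re-analysed and new libraries, so stage and library origin cannot be told apart on it. The second component held 35.1% and separated hESC from hDE. The third component held 11.3% and placed hAFE apart from hPFE. Replicates of the same stage correlated at 0.988 in hESC, 0.985 in hDE, 0.959 in hAFE and 0.959 in hPFE (Pearson, across genes, which are not independent replicates). The log2 difference between replicates had an SD of 0.31 in hESC, 0.27 in hDE, 0.59 in hAFE and 0.56 in hPFE over 9852 genes at a mean of 10 CPM or more, so the 2 new stages were less tightly replicated. Genes more than 2 fold apart between replicates numbered 54 in hESC, 50 in hDE, 600 in hAFE and 523 in hPFE.

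**Figure D1:**
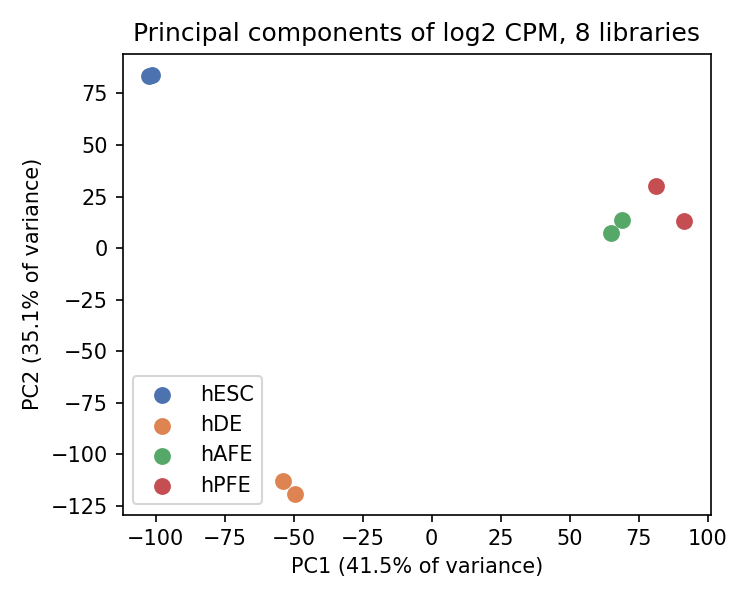
Each point is a library, placed by the first principal component (41.5% of variance, horizontal axis) and the second (35.1%, vertical axis) of log2 CPM, and coloured by stage. The 2 libraries of each stage sit together, and hAFE and hPFE lie close to each other on both axes.

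The first comparison asks what changed when stem cells became definitive endoderm. Endoderm regulators rose from near absence while core pluripotency genes fell. SOX17 (chromosome 8, 54457935 to 54460888), a transcription factor of endoderm, was at 0.0848 ± 0.12 CPM in hESC and 137.5 ± 15.6 CPM in hDE, with 3 counts in total in hESC, a ratio of 1590 (95% counting interval 543 to 7700; adjusted p = 2.01e-05). FOXA2 (chromosome 20, 22581005 to 22585455), a forkhead factor of foregut endoderm, was at 0.0866 ± 0.0375 CPM in hESC and 27.6 ± 0.0501 in hDE, a ratio of 316 (108 to 1540; adjusted p = 0.000173). CXCR4 (chromosome 2, 136114349 to 136118165), a chemokine receptor used as a surface marker of definitive endoderm, rose from 0.765 ± 0.362 to 639.8 ± 48.3 CPM (log2 fold change 9.70, SE 0.783, adjusted p = 0.000135). POU5F1 (chromosome 6, 31164337 to 31180731), which encodes the pluripotency factor OCT4, fell from 900.1 ± 59.5 to 18.4 ± 10.5 CPM (log2 fold change -5.61, SE 0.405, adjusted p = 9.12e-05). SOX2 (chromosome 3, 181711924 to 181714436) fell from 129.9 ± 0.523 to 0.819 ± 0.276 CPM, and NANOG (chromosome 12, 7787794 to 7799141) fell less, from 131.7 ± 10.4 to 43.2 ± 5.64 CPM (log2 fold change -1.61, SE 0.229, adjusted p = 0.00143). PAX9, a paired-box gene of pharyngeal pouches, rose from 0.115 ± 0.0774 to 3.81 ± 2.42 CPM (adjusted p = 0.00827), a call lost without the first hESC library and on log2(TPM + 1). TBX1 had no counts in either stage.

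Gene groups fixed beforehand moved with these landmarks. Of 19 measured genes of the definitive endoderm list, 18 rose and 1 did not pass, and the counts were the same adjusted over the list alone. The list was called higher by camera (adjusted p = 7.5e-10), a call lost with adjusted p = 0.132 with an estimated correlation. That correlation was -0.0401, below the preset 0.01, so correlated genes do not account for this loss. CER1, a secreted Nodal and BMP antagonist, rose from 1.91 ± 0.742 to 7607 ± 549 CPM, and GATA6 had 3 counts in hESC and 241.8 ± 0.204 CPM in hDE. FOXA3 did not pass, at 13.3 CPM in hESC and 17.9 in hDE. Of 11 extraembryonic endoderm genes, markers of another lineage, 8 rose and 1 fell, against 8 and 2 adjusted over the list alone (adjusted p = 0.015; adjusted p = 0.343 with an estimated correlation). Of 8 endothelial and blood genes 3 fell, also adjusted over the list alone (adjusted p = 0.0309; adjusted p = 0.346 with an estimated correlation), a call lost on log2(TPM + 1) (adjusted p = 0.184). Not called were the neural (adjusted p = 0.841), neural crest (0.184), surface and placodal ectoderm (0.571), cardiac and lateral mesoderm (0.256), paraxial mesoderm (0.862), mesenchyme (0.841), amnion and trophoblast (0.409) and liver and pancreas (0.271) lists. On log2(TPM + 1) the cardiac and lateral mesoderm and the liver and pancreas lists were called higher (adjusted p = 0.0163 and 0.0396). Of 17 anterior foregut genes 9 rose and 1 fell, against 10 and 1 adjusted over the list alone (adjusted p = 0.0151; adjusted p = 0.342 with an estimated correlation). All 9 measured mesendoderm and primitive streak genes rose, also when adjusted over the list alone (adjusted p = 9.15e-07; adjusted p = 0.159 with an estimated correlation). Among them EOMES rose from 0.574 ± 0.387 to 270.2 ± 10.1 CPM and NODAL from 1.16 ± 0.28 to 281.3 ± 49.6 CPM. Of 13 Nodal and activin pathway genes 9 rose and 2 fell, with the same counts adjusted over the list alone (adjusted p = 0.000767; adjusted p = 0.407 with an estimated correlation). LEFTY2, a Nodal antagonist, rose from 2.09 ± 1.2 to 3650 ± 200 CPM, and LEFTY1 from 1.98 ± 1.11 to 737.6 ± 203 CPM. GDF3 fell at adjusted p = 0.0489, a call lost in 7 of 18 alternatives, among them DESeq2 and the replicate block.

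Pluripotency genes did not all fall. Of 24 measured members 18 fell and 2 rose, with the same counts adjusted over the list alone (adjusted p = 7.05e-05; adjusted p = 0.175 with an estimated correlation). SFRP2 fell from 80.8 ± 4.12 to 0.476 ± 0.0438 CPM. THY1, a surface antigen of stem cells, fell from 303.6 ± 5.06 to 7.87 ± 1.68 CPM. SALL4 rose from 214.3 ± 3.45 to 340.8 ± 10.7 CPM (adjusted p = 0.00774), a call lost in 3 of 18 alternatives, among them log2(TPM + 1). LIN28A did not pass, at 1469 ± 107 CPM in hESC and 1434 ± 28 in hDE.

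Metabolic and cell cycle groups also differed between hDE and hESC. All 18 measured cholesterol synthesis genes fell, also when adjusted over the list alone (adjusted p = 1.1e-06; adjusted p = 0.434 with an estimated correlation). INSIG1, a sterol-regulated brake on that pathway, fell from 92.98 ± 30.2 to 10.9 ± 0.168 CPM. Of 15 integrated stress response genes 12 rose and none fell, against 13 adjusted over the list alone (adjusted p = 0.000703; adjusted p = 0.413 with an estimated correlation). DDIT3 rose from 8.23 ± 6.12 to 79.9 ± 3.54 CPM and HERPUD1 from 18.8 ± 3.61 to 144.8 ± 32.5 CPM. Of 22 proliferation genes 12 fell and 1 rose, against 13 and 1 adjusted over the list alone (adjusted p = 0.00169; adjusted p = 0.515 with an estimated correlation). The replication helicase genes MCM4, MCM3 and MCM2 fell by 1.62, 1.40 and 1.39 on the log2 scale, while MCM6 rose by 0.56, a call lost in 5 of 18 alternatives, and MKI67 did not pass at 118.8 CPM in hESC and 143 in hDE. Of 9 replication-dependent histone genes 4 fell, against 5 adjusted over the list alone, and the list itself was not called (adjusted p = 0.0658). It was called lower on log2(TPM + 1) (adjusted p = 0.00465). Of 18 basement membrane genes 10 rose and 2 fell, against 11 and 3 adjusted over the list alone (adjusted p = 0.0316; adjusted p = 0.507 with an estimated correlation), among them COL4A1, from 126.4 ± 6.81 to 641.1 ± 86.8 CPM.

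In total 7304 of 17446 genes differed between hDE and hESC, 3533 higher and 3771 lower in hDE, and 4931 of them by at least 2 fold. Among genes at 10 CPM or more in the higher stage with both libraries above both of the other stage, the largest rises were in PRSS2, LINC00261, ASB5 and NPPB. PRSS2, a trypsinogen gene with close paralogs, was at 0 counts in hESC and at least 821-fold higher in hDE. LINC00261, whose counts are uncertain and whose call was lost on log2(TPM + 1), and ASB5 were at least 580-fold and 557-fold higher, and NPPB rose from 0.117 ± 0.005 to 689.2 ± 95.5 CPM. The largest falls were in SYT6, SPTSSB and TNFSF11, with 0 counts in hDE and at least 266-fold, 104-fold and 94.6-fold lower, and in ZDHHC22, which had 1 count in hDE and a ratio of 1010 (181 to 39900). The count of calls was 3879 to 4133 when a hESC or hDE library was left out.

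The second comparison asks what changed from definitive endoderm to anterior foregut. Endoderm landmarks such as SOX17 fell, and SOX2 rose. SOX2, which marks anterior foregut as well as stem cells, rose from 0.819 ± 0.276 to 107.7 ± 71.4 CPM (adjusted p = 0.00021). SOX17 fell from 137.5 ± 15.6 to 0.139 ± 0.00996 CPM, CXCR4 from 639.8 ± 48.3 to 32.9 ± 25.2 CPM, POU5F1 from 18.4 ± 10.5 to 0.418 ± 0.0299 CPM, and NANOG from 43.2 ± 5.64 CPM to 3 counts in hAFE, a ratio of 418 (143 to 2030). FOXA2 did not pass, at 27.6 ± 0.0501 CPM in hDE and 29.4 ± 16.6 in hAFE (adjusted p = 0.888). PAX9 rose from 3.81 ± 2.42 to 23.6 ± 2.53 CPM (adjusted p = 0.0161), a call lost without the second hDE library. TBX1, a T-box gene of pharyngeal endoderm and mesoderm, went from 0 counts to 3.36 ± 3.73 CPM, at least 26.9-fold higher, and its call (adjusted p = 0.0239) was lost in 4 of 18 alternatives.

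Endoderm and streak groups fell in hAFE. All 9 mesendoderm and primitive streak genes fell, also adjusted over the list alone (adjusted p = 2.09e-07; adjusted p = 0.157 with an estimated correlation), with EOMES at 0.249 ± 0.165 CPM and NODAL at 0.139 ± 0.00996 CPM. Of 13 Nodal and activin pathway genes 10 fell and none rose, against 11 adjusted over the list alone (adjusted p = 1.99e-08; adjusted p = 0.335 with an estimated correlation), and LEFTY2 dropped to 0.67 ± 0.293 CPM. Of 19 definitive endoderm genes 13 fell and 2 rose, with the same counts adjusted over the list alone (adjusted p = 6.64e-06; adjusted p = 0.157 with an estimated correlation). CER1 fell to 2.75 ± 1.28 CPM, and FOXA1, a forkhead relative of FOXA2, rose from 6.51 ± 0.522 to 52.6 ± 36.7 CPM, a call lost without the first hDE library. Of 15 integrated stress response genes 12 fell, against 15 adjusted over the list alone (adjusted p = 7.14e-06; adjusted p = 0.343 with an estimated correlation). TRIB3 fell from 80.1 ± 17.9 to 8.48 ± 4.24 CPM and DDIT3 from 79.9 ± 3.54 to 8.60 ± 2.53 CPM. Of 24 pluripotency genes 13 fell and 2 rose, against 13 and 3 adjusted over the list alone (adjusted p = 0.000199; adjusted p = 0.175 with an estimated correlation). LIN28A and TRIM71 did not pass and stayed at 1129 ± 193 and 297.8 ± 32.3 CPM in hAFE.

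Pharyngeal, retinoic acid and HOX groups rose in hAFE. Of 24 pharyngeal endoderm genes 14 rose and 2 fell, against 17 and 2 adjusted over the list alone (adjusted p = 0.000703; adjusted p = 0.343 with an estimated correlation). ISL1 rose from 0.25 ± 0.149 to 22.5 ± 24.4 CPM, a call lost without the second hDE library, and HHEX fell from 32.4 ± 3.99 to 1.525 ± 1.88 CPM. Of 17 retinoic acid response genes 12 rose, against 14 adjusted over the list alone (adjusted p = 0.00016; adjusted p = 0.36 with an estimated correlation). MEIS2, a HOX cofactor, rose from 0.941 ± 0.306 to 174.6 ± 140 CPM, and HOXB2 went from 0 counts to 4.91 ± 4.36 CPM. CYP26A1, which degrades retinoic acid, did not pass at 1733 ± 175 CPM in hDE and 211.2 ± 287 in hAFE. Of 13 anterior HOX and cofactor genes 8 rose, against 10 adjusted over the list alone (adjusted p = 0.000175; adjusted p = 0.434 with an estimated correlation). Of 9 hedgehog response genes 5 rose, also adjusted over the list alone (adjusted p = 0.04; adjusted p = 0.346 with an estimated correlation), among them the pathway target PTCH1, from 17.4 ± 1.93 to 88.7 ± 24.8 CPM. On log2(TPM + 1) these 4 lists were no longer called, with adjusted p = 0.954, 0.118, 0.129 and 0.217. That scale had no TMM scaling and was off centre here. The median log2 fold change of all genes was 0.496 on it, against 0.0123 with counts.

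Of the lists of other lineages, 2 were called in hAFE. Those not called were neural (adjusted p = 0.976), neural crest (0.907), cardiac and lateral mesoderm (0.6), paraxial mesoderm (0.764), endothelial and blood (0.829), mesenchyme (0.965), extraembryonic endoderm (0.66) and liver and pancreas (0.354). On log2(TPM + 1) the extraembryonic endoderm and the liver and pancreas lists were called lower (adjusted p = 0.0369 and 0.00409). Of 11 surface and placodal ectoderm genes 6 rose, also adjusted over the list alone (adjusted p = 0.00116; adjusted p = 0.434 with an estimated correlation), including GRHL2, which reached 88.9 ± 6.45 CPM. Of 10 amnion and trophoblast genes 6 rose, also adjusted over the list alone (adjusted p = 0.00434; adjusted p = 0.343 with an estimated correlation). CGA, the shared hormone alpha chain, was at 36.8 ± 45.5 CPM and ELF5 at 9.65 ± 1.03 CPM, both from 0 counts in hDE. On log2(TPM + 1) neither of these 2 was called (adjusted p = 0.513 and 0.915), and the second had the opposite direction. Of 18 cholesterol synthesis genes 9 rose, against 11 adjusted over the list alone (adjusted p = 0.000211; adjusted p = 0.515 with an estimated correlation). Of 22 proliferation genes 8 rose, against 9 adjusted over the list alone (adjusted p = 0.0115; adjusted p = 0.614 with an estimated correlation). Of 9 replication-dependent histone genes 3 rose, against 4 adjusted over the list alone. That list was not called (adjusted p = 0.0504), but was called higher on log2(TPM + 1) (adjusted p = 0.00465). As a mark of RNA content, 9 of 13 mitochondrial messenger genes fell in hAFE, also adjusted over the list alone (adjusted p = 0.00502; adjusted p = 0.638 with an estimated correlation), and the 4 largest of these falls had the opposite sign, uncalled, on log2(TPM + 1), where the list was not called (adjusted p = 0.223).

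In total 5267 genes differed between hAFE and hDE, 2609 higher and 2658 lower in hAFE, and 3530 by at least 2 fold. The largest rises by the same rule were CGA, HOTAIRM1, SYT6 and CA10, each with 0 counts in hDE and at least 293-fold, 258-fold, 157-fold and 116-fold higher. CA10 was at 14.61 ± 20.4 CPM in hAFE and lost its call in 10 of 18 alternatives, and CGA and HOTAIRM1 (29.62 ± 36.6 CPM) lost theirs without either hDE library. The falls were led by the 7SL gene RN7SL1, which is uncertain because near-identical copies can share its reads, and by LINC00458, at 171 ± 22.3 CPM in hDE and at least 1630-fold lower in hAFE. The RN7SL1 call was lost in 5 of 17 alternatives, among them the voom weight per stage. Leaving out hDE replicate 1 or 2 gave 2544 or 2512 calls. The 2 stages also differ in library origin, which cannot be told apart from the stage here.

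The third comparison asks what changed between anterior foregut and pharyngeal foregut, within the new libraries. PAX1, SHH and FN1 rose, and LIN28A fell. With only the 4 hAFE and hPFE libraries the calls of PAX1, SHH and LIN28A were lost, and that of PAX1 also with DESeq2. PAX1 (chromosome 20, 21705659 to 21718486), a paired-box gene of pharyngeal pouches, rose from 0.329 ± 0.465 to 21.9 ± 6.47 CPM (log2 fold change 6.07, SE 0.932, adjusted p = 0.0161). SHH (chromosome 7, 155799986 to 155812273), a secreted signal of foregut epithelium, rose from 11.2 ± 3.55 to 119.8 ± 66.6 CPM (log2 fold change 3.42, SE 0.428, adjusted p = 0.0062). FOXE1 rose from 2.98 ± 2.82 to 46.6 ± 28.8 CPM (adjusted p = 0.0224), a call lost in 6 of 18 alternatives. FN1 (chromosome 2, 215360440 to 215436172), fibronectin, rose from 322 ± 61.8 to 8693 ± 4170 CPM (log2 fold change 4.75, SE 0.363, adjusted p = 0.00134). LIN28A (chromosome 1, 26410778 to 26429722), an RNA-binding repressor of let-7, fell from 1129 ± 193 to 160.4 ± 60.8 CPM (log2 fold change -2.82, SE 0.271, adjusted p = 0.00285).

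No landmark passed in this comparison. SOX2 was at 107.7 ± 71.4 CPM in hAFE and 108.1 ± 17.3 in hPFE, FOXA2 at 29.4 ± 16.6 and 17.8 ± 7.15, PAX9 at 23.6 ± 2.53 and 62.1 ± 47.4, TBX1 at 3.36 ± 3.73 and 1.58 ± 0.519, and CXCR4 at 32.9 ± 25.2 and 10.8 ± 4.8. POU5F1, NANOG and SOX17 stayed under 0.5 CPM in both stages.

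Of 13 measured EMT genes 6 rose and none fell in hPFE, against 10 adjusted over the list alone (adjusted p = 9.15e-07; adjusted p = 0.157 with an estimated correlation). MMP2, a matrix protease, rose from 15.35 ± 2.68 to 124.2 ± 26.4 CPM and SNAI2, a repressor of epithelial genes, from 0.645 ± 0.396 to 9.40 ± 6.6 CPM, while CDH2 did not pass at 357.9 and 368.7 CPM. Of 12 mesenchyme genes, markers of another cell type, 6 rose, against 8 adjusted over the list alone (adjusted p = 0.000316; adjusted p = 0.342 with an estimated correlation). COL1A1 rose from 5.67 ± 1.29 to 73.8 ± 15.4 CPM. COL3A1 was at 1232 CPM in hPFE replicate 1 and 29.73 in replicate 2, and LUM at 11.41 and 87.45, and the COL3A1 call was lost in 10 of 18 alternatives. Of 10 amnion and trophoblast genes 1 rose, against 7 higher and 1 lower adjusted over the list alone (adjusted p = 0.0131; adjusted p = 0.36 with an estimated correlation). Of 8 endothelial and blood genes 1 rose, against 3 adjusted over the list alone (adjusted p = 0.0481; adjusted p = 0.36 with an estimated correlation; adjusted p = 0.0564 with the replicate block). On log2(TPM + 1) these 2 lists were not called (adjusted p = 0.217 and 0.375). Lists of other lineages that were not called were neural (adjusted p = 0.741), neural crest (0.216), surface and placodal ectoderm (0.223), cardiac and lateral mesoderm (0.844), paraxial mesoderm (0.575), extraembryonic endoderm (0.0894) and liver and pancreas (0.738). Of 18 basement membrane genes 6 rose, against 8 adjusted over the list alone (adjusted p = 0.000466; adjusted p = 0.36 with an estimated correlation). Of 18 epithelial junction genes 2 rose and none fell, also adjusted over the list alone (adjusted p = 0.0115; adjusted p = 0.456 with an estimated correlation). CDH1, E-cadherin, rose from 112.5 ± 18.7 to 253.1 ± 44.5 CPM.

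Of 13 Nodal and activin pathway genes 6 rose, against 7 adjusted over the list alone (adjusted p = 0.000199; adjusted p = 0.36 with an estimated correlation). PMEPA1, a feedback target of TGF-beta signalling, rose from 0.209 ± 0.0149 to 17.2 ± 2.28 CPM (log2 fold change 6.31, SE 0.3, adjusted p = 0.000271). Of 15 BMP response genes 2 rose, against 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.015; adjusted p = 0.579 with an estimated correlation), and the antagonist NOG rose from 0.421 ± 0.128 to 9.98 ± 2.79 CPM. ID3 did not pass, at 53.85 ± 14.8 CPM in hAFE and 122.1 ± 84.6 in hPFE (adjusted p = 0.14). Of 12 WNT response genes 2 rose, also adjusted over the list alone (adjusted p = 0.00261; adjusted p = 0.306 with an estimated correlation), and LGR5 had 1 count in hAFE and 7.49 ± 0.393 CPM in hPFE. The other call, TNFRSF19, was lost in 8 of 18 alternatives. AXIN2 did not pass, at 13.66 ± 6.29 CPM in hAFE and 17.94 ± 0.647 in hPFE (adjusted p = 0.458). Of 13 Notch response genes 4 rose and 1 fell, against 5 and 1 adjusted over the list alone (adjusted p = 0.00769; adjusted p = 0.495 with an estimated correlation). Among the risers, the calls of HEY1, JAG1 and NOTCH1 were lost in 8, 8 and 10 of 18 alternatives. HES1 and HES4 did not pass (adjusted p = 0.209 and 0.609). Of 22 proliferation genes 5 fell, against 7 adjusted over the list alone (adjusted p = 0.000834; adjusted p = 0.507 with an estimated correlation), with MCM5 lower by a log2 fold change of -0.97. Of 18 cholesterol synthesis genes 2 fell, against 4 lower and 1 higher adjusted over the list alone (adjusted p = 0.00237; adjusted p = 0.614 with an estimated correlation). Of 24 pluripotency genes 3 fell, against 4 lower and 1 higher adjusted over the list alone (adjusted p = 0.031; adjusted p = 0.343 with an estimated correlation), namely LIN28A, TRIM71 and SALL4. The pharyngeal endoderm list had 4 of 24 genes higher, against 4 higher and 3 lower adjusted over the list alone, and was not called (adjusted p = 0.438). Of 8 thymus and parathyroid genes 3 rose, against 4 adjusted over the list alone (adjusted p = 0.04; adjusted p = 0.434 with an estimated correlation). None of 17 retinoic acid response genes passed, at adjusted p = 0.977 for the list by camera, and 0 passed adjusted over the list alone.

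In total 1306 genes differed between hPFE and hAFE, 833 higher and 473 lower in hPFE, and 907 by at least 2 fold. This count rests on the spread shared by all 8 libraries. With only the 4 hAFE and hPFE libraries 56 genes were called, 55 of them among the 1306. The list tests of this comparison, and the counts adjusted over each list alone, also take their spread from all 8 libraries. They were not repeated with those 4 libraries alone, so how far they depend on the shared spread was not tested. With a limma voom weight per stage, chosen after seeing the data, 447 genes were called, and of the 49 called genes that the naming rule took, 9 kept their call in every alternative, among them ACTA1, PTPN5, LGR5, FN1, MMP2, COL1A1, PMEPA1 and NOG. Every other one except AL356488.2 was lost with the 4 libraries alone. Leaving out either hESC or hDE library gave 496 to 569 calls. The largest rises by rule were ADGRF4, CYP24A1 and PTHLH, with 0 counts in hAFE and at least 234-fold, 118-fold and 104-fold higher, and GPRC5A. The CYP24A1 call was lost in 9 of 18 alternatives. The largest falls were AL356488.2, whose counts are uncertain, with 0 counts in hPFE and at least 140-fold lower, PAQR9, lost in 11 of 18 alternatives, ACTA1, from 120.6 ± 20.4 to 4.31 ± 1.55 CPM, and PTPN5, from 35.3 ± 7.39 to 1.28 ± 0.077 CPM.

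The fourth comparison sets the end point against the starting cells. POU5F1 was at 900.1 ± 59.5 CPM in hESC and had 1 count in hPFE, a ratio of 27300 (4910 to 1080000), NANOG had 3 counts in hPFE, a ratio of 1330 (454 to 6450), and SOX2 did not pass at 129.9 ± 0.523 and 108.1 ± 17.3 CPM (adjusted p = 0.612). PAX9 (chromosome 14, 36657568 to 36679715) rose from 0.115 ± 0.0774 to 62.1 ± 47.4 CPM (log2 fold change 8.96, SE 0.939, adjusted p = 0.000449). FOXA2 had 3 counts in hESC and a ratio of 209 (71.2 to 1020), CXCR4 rose from 0.765 ± 0.362 to 10.8 ± 4.8 CPM, and TBX1 (chromosome 22, 19756703 to 19783593) was at least 17.7-fold higher from 0 counts, with its call (adjusted p = 0.0249) lost in 4 of 18 alternatives. SOX17 did not pass.

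Of 24 pluripotency genes 22 fell and 1, KLF4, rose, with the same counts adjusted over the list alone (adjusted p = 4.53e-11; adjusted p = 0.132 with an estimated correlation). The KLF4 call was lost without either hESC library. Of 24 pharyngeal endoderm genes 16 rose and 1, FGF19, fell, against 17 and 1 adjusted over the list alone (adjusted p = 5.76e-05; adjusted p = 0.342 with an estimated correlation). PAX1 was at least 255-fold higher from 0 counts. Of 17 anterior foregut genes 12 rose, also adjusted over the list alone (adjusted p = 0.000199; adjusted p = 0.175 with an estimated correlation), and FOXA1 was at least 601-fold higher. Of 17 retinoic acid response genes 12 rose, also adjusted over the list alone (adjusted p = 6.22e-05; adjusted p = 0.346 with an estimated correlation), with MEIS1 from 0.316 ± 0.192 to 140.1 ± 62.7 CPM. Of 15 BMP response genes 14 rose, also adjusted over the list alone (adjusted p = 5.76e-05; adjusted p = 0.416 with an estimated correlation), while ID3 did not pass. Of 18 basement membrane genes 15 rose, also adjusted over the list alone (adjusted p = 9.15e-07; adjusted p = 0.342 with an estimated correlation), and 16 of 18 cholesterol synthesis genes fell, also adjusted over the list alone (adjusted p = 6.05e-05; adjusted p = 0.502 with an estimated correlation). Of 22 proliferation genes 13 fell, against 14 adjusted over the list alone (adjusted p = 0.00254; adjusted p = 0.519 with an estimated correlation), a call lost on log2(TPM + 1) (adjusted p = 0.137). Of 13 mitochondrial messenger genes 5 fell, also adjusted over the list alone, and that list was not called (adjusted p = 0.106). Beside these, 10 of 11 surface and placodal ectoderm genes rose, also adjusted over the list alone (adjusted p = 3.33e-05; adjusted p = 0.36 with an estimated correlation), with TP63 at 27.8 ± 18.8 CPM in hPFE, and 7 of 12 mesenchyme genes rose, also adjusted over the list alone (adjusted p = 0.00161; adjusted p = 0.343 with an estimated correlation).

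In total 7842 genes differed between hPFE and hESC, 3773 higher and 4069 lower in hPFE, and 5045 by at least 2 fold. The largest rises by rule were ITGB6, FOXA1 and CNTN5, at least 823-fold, 601-fold and 339-fold higher from 0 counts, and TCIM. After POU5F1 the largest falls were AL117378.1, D21S2088E and AC009446.1, at least 681-fold, 621-fold and 380-fold lower. Leaving out hESC replicate 1 or 2 gave 4599 or 4043 calls, and library origin cannot be told apart from stage in this comparison either.

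**Figure D2:**
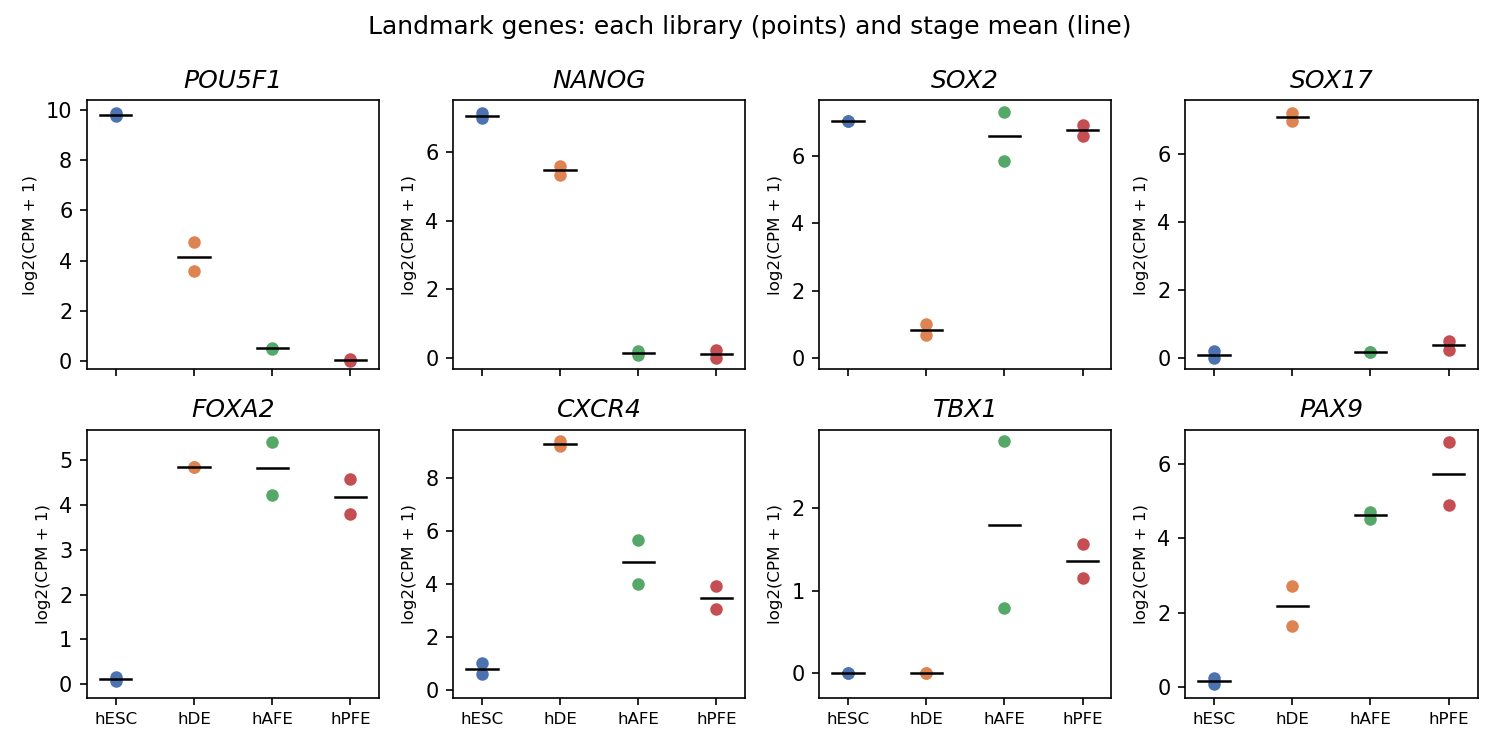
Each panel plots log2(CPM + 1) of a landmark gene (vertical axis) at the 4 stages (horizontal axis), with a point per library and a line at the stage mean. POU5F1 falls from hESC onwards, SOX17 is high in hDE alone, SOX2 is low in hDE alone, and PAX9 is higher in hAFE and hPFE than in hESC.

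Genes higher in a single stage than in each of the other stages numbered 1690 for hESC, 1115 for hDE, 89 for hAFE and 356 for hPFE. With each library left out in turn they ran from 687 to 1937, 551 to 1251, 22 to 141 and 156 to 414. Those of hDE included CER1, LEFTY2, FGF17, EOMES and SOX17. Every stage was also compared with stages of the other library origin. Origin therefore enters each of these counts and cannot be told apart from stage in those comparisons. The steps from hESC to hDE and from hAFE to hPFE share no library, but both take each gene's spread from the same fit, so the value for independent lists is not a value for no relation. Of the genes that rose in the first step 245 also rose in the later one, against 168.7 for independent lists, and 178 fell in both against 102.2. Another 102 rose then fell, against 95.79, and 237 fell then rose, against 180.1. Among changes of at least 2 fold 168 rose in both, against 92.25, 65 fell in both, against 32.95, 52 rose then fell, against 30.08, and 198 fell then rose, against 101.1.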

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

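Under RLE scaling, DESeq2, the filter of 1 CPM in 2 libraries, effective length offsets and the omission of small structural, mitochondrial and histone genes, each of the 4 counts of calls stayed between 0.74 and 1.48 times its value. The hPFE vs hAFE count of 1306 was the least stable: 3234 with no count filter, 812 on log2(TPM + 1), 447 with voom weights per stage (chosen after seeing the data) and 56 with only its own 4 libraries. Those libraries vary by a common coefficient of 31.7%, against 11.2% in hESC and hDE, where the 4-library fit called 10197 genes. Leaving out a library gave 3879 to 8328 calls for hDE vs hESC, 2512 to 6354 for hAFE vs hDE, 496 to 1586 for hPFE vs hAFE and 4043 to 8309 for hPFE vs hESC; fewer libraries enter each fit. Stage-high genes then ran from 687 to 1937 (hESC), 551 to 1251 (hDE), 22 to 141 (hAFE), 156 to 414 (hPFE) and 1606 to 3619 in total. A minimum of 2 fold, which removes smaller changes, left 5045 hPFE vs hESC calls, stage-high genes of 1007 in hESC, 692 in hDE, 47 in hAFE and 2024 in total, and overlaps of 65 for genes lower in both steps, 52 for higher then lower, and 483 in all. On the log2(TPM + 1) scale the median log2 fold change of all genes was -0.27 (hDE vs hESC), 0.50 (hAFE vs hDE), 0.14 (hPFE vs hAFE) and 0.36 (hPFE vs hESC), against -0.01, 0.01, -0.03 and 0.02 with counts. It moved the higher share of calls from 48.4%, 49.5%, 63.8% and 48.1% to 18.1%, 88.8%, 89.4% and 78.7%. On that scale MT-CO3, MT-ATP8, MT-CO2 and MT-ND4 changed sign in hAFE vs hDE (0.12, 0.10, 0.15 and 0.19, none called), and the amnion and trophoblast list turned downward (adjusted p = 0.915); the 4 genes lay below the median of all genes there. Of 65 list calls, 44 held on log2(TPM + 1), 62 with the replicate block and 0 with an estimated correlation. Another 17 list tests that were not among the 65 were called on log2(TPM + 1).

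With the replicate block the counts were 6909, 4941, 1072 and 7494. Same-numbered libraries deviated with correlations from -0.041 to 0.061, so they showed no shared deviation. This does not settle whether they were paired, since paired libraries need not share a deviation. Of the called named genes, 43 of 61 (hDE vs hESC), 35 of 58 (hAFE vs hDE), 9 of 49 (hPFE vs hAFE) and 38 of 45 (hPFE vs hESC) kept their call in every alternative that tested them.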

Other observations

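Other fixed groups moved as well. Of 15 DNA methylation and imprinted genes 9 rose and 1 fell in hAFE against hDE, with the same counts adjusted over the list alone (adjusted p = 0.0124; adjusted p = 0.346 with an estimated correlation). H19 was at 0.117 CPM in hDE and 180 in hAFE, and IGF2 at 1.43 and 118.9, while DNMT3B, a de novo methyltransferase, was at 950.8 CPM in hESC, 184.5 in hDE, 31.76 in hAFE and 16.54 in hPFE. Of 17 glycolysis and hypoxia genes 8 fell and 2 rose in the same step, also adjusted over the list alone (adjusted p = 0.0124; adjusted p = 0.456 with an estimated correlation), and the glucose transporter gene SLC2A3 was at 4426 CPM in hDE and 212.5 in hAFE. Of 15 p53 target and apoptosis genes 9 rose and 2 fell in hPFE against hESC, also adjusted over the list alone (adjusted p = 0.0321; adjusted p = 0.631 with an estimated correlation; adjusted p = 0.0553 on log2(TPM + 1)), and MDM2 was at 133.9 CPM in hESC and 788 in hPFE. These examples were chosen after their values were seen. They are given without SD or adjusted p, so they do not show which changes were called. In both of these comparisons library origin cannot be told apart from stage.

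Lists of other cell types gave mixed counts. In hPFE against hESC, 7 of 10 cardiac and lateral mesoderm genes rose, against 8 adjusted over the list alone (adjusted p = 0.0119; adjusted p = 0.424 with an estimated correlation), 8 of 10 amnion and trophoblast genes rose and 1 fell, also adjusted over the list alone (adjusted p = 0.00367; adjusted p = 0.343 with an estimated correlation), and 5 of 9 thyroid and lung genes rose, also adjusted over the list alone (adjusted p = 0.04; adjusted p = 0.413 with an estimated correlation). On log2(TPM + 1) these 3 lists were not called (adjusted p = 0.176, 0.223 and 0.154). Of 11 extraembryonic endoderm genes 6 rose and 1 fell, against 7 and 1 adjusted over the list alone (adjusted p = 0.0124; adjusted p = 0.342 with an estimated correlation; adjusted p = 0.118 on log2(TPM + 1)). The neural list (2 higher and 1 lower of 8; adjusted p = 0.841), the neural crest list (4 higher and 3 lower of 9; adjusted p = 0.801), the paraxial mesoderm list (3 higher and 2 lower of 5; adjusted p = 0.626), the endothelial and blood list (3 higher and 4 lower of 8; adjusted p = 0.626) and the liver and pancreas list (1 higher and 2 lower of 9; adjusted p = 0.927) were not called. Of these, the endothelial and blood list was called lower on log2(TPM + 1) (adjusted p = 0.0427).

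The tests below were chosen after the results were seen, except the simulation, which was chosen and its outcome predicted before it was run, although after the 2 counts of calls had been seen. The hPFE vs hAFE count fell from 1306 to 56 when the tighter hESC and hDE libraries were left out of the fit. That fit lacks their spread and also has fewer residual degrees of freedom, and the 2 effects were not separated. False calls from a shared spread that is too small could account for part of the 1306. Counts simulated with no difference between hAFE and hPFE, using the spread of each origin, gave a mean of 6.15 calls over 20 simulations, with at most 19. The simulation rests on estimated spreads that were themselves smoothed across genes, so it does not exclude that explanation. A real stage difference that is hard to resolve with 2 variable libraries per stage stays open, and these cannot be told apart with these libraries.

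In hPFE against hAFE 6 of 12 mesenchyme and 6 of 13 EMT genes were called higher and the others did not pass, and both list calls were lost with an estimated correlation (adjusted p = 0.342 and 0.157). A single population of mesenchymal cells with a fixed profile, at different shares in the 2 hPFE libraries, would move its markers together, but the log2 ratios between the hPFE replicates spanned 8.31 over the 6 called mesenchyme genes, from COL3A1 higher in replicate 1 to LUM higher in replicate 2. A lower share of epithelial cells cannot be told apart: the epithelial junction list had a median log2 fold change of 0.369 with no member lower, but genes with a high baseline would hide a small loss. TGF-beta family signalling within the cells is a hypothesis that may fit the rise of PMEPA1 and SKIL, with 6 of 13 genes of the Nodal and activin list higher and none lower (adjusted p = 0.000199). The adjusted p of 0.36 with an estimated correlation decides nothing, since no list call held in that form, and whole-culture RNA does not place these transcripts in a cell, so mixed mesenchymal populations stay open too.

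RN7SL1 had 0 counts in hAFE and 33100 ± 8130 CPM in hDE. The summed CPM of RN7SL1, RN7SL2 and AL139099.4 was 90600 ± 19300 in hAFE and 201400 ± 10000 in hDE, a log2 ratio of -1.15, but it also differed between the 2 hPFE libraries (107733 and 35191.2). Counts split unevenly between near-identical copies could leave a single copy at 0, and with a sum that varies this much within a stage it cannot be told apart from a fall of these RNAs. In hESC the RN7SL1 level was 0 in the first library and 30870 CPM in the second. AL139099.4 was at 61212 and 24277.6 CPM there, and the sum of the copies at 120699 and 107943. A 0 of RN7SL1 alone therefore does not show a low sum. What stays open is the lower sum in hAFE than in hDE.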
